A study of Homo sapiens with 2 samples.

How the data were processed

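CUT&Tag was performed in PLC8024 cells, a human liver cancer cell line, in 1 control library and 1 library from cells exposed to a drug at 10 nM for 6 hours, per the labels. CUT&Tag maps a chromatin protein or mark by steering a transposase to an antibody bound in permeable nuclei, and the inserted fragments are amplified and sequenced. The labels name neither the drug nor the antibody used for these 2 libraries. The design text also describes IgG and Pol II control groups, and these were not analysed here.

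Each library came as 1 table of peaks, annotated with HOMER against hg38 from a MACS2 narrow peak file whose name points to duplicate removal, per the file headers. Peaks were therefore called per library and not on pooled libraries. The measurement deposited by the authors for each peak was its score, a whole number that by the convention of MACS2 is 10 times the −log10 of the q-value. The lowest score in both lists was 13, which by that convention is a q-value of 0.0501. Aligner, software versions, duplicate removal settings and the use of an IgG control in peak calling were not given in the sources used here. The files hold no read totals, coverage or fold enrichment, so the depth of both libraries was unknown. A deeper library passes a fixed q-value at weaker sites, so peak numbers, peak widths and scores can all move with depth. Scores were used to rank, describe or filter peaks within their own list. Control scores also served to match control peaks or genes by strength before drug overlap or drug scores were compared among them. In the control list 1 line was emptied before this work and was not analysed here.

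Samples were assigned to groups by their titles. Peaks were compared by position with 1-based hg38 coordinates as given in the files, and a peak counted as overlapped when it shared at least 1 bp with a peak of the other list. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, since PCR reads are not independent molecules and neighbouring peaks are not independent events. Peaks were split into 10 bins of equal size by score within their list, and control promoter genes likewise. A promoter peak was one that the authors' annotation placed in the promoter class. Its gene was the nearest gene named there, and 18453 of 18487 gene identifiers were matched to current symbols in a RefSeq table of GRCh38.p14, the same build. Promoter peaks without a gene name, 30 in control and 23 in drug, were left out of gene counts. A gene was compared by name, as planned, and also by position, an alternative added after the data had been seen, because the same site can be given to a neighbouring gene, or to another annotation class, where its peak differs in extent between the lists. By position, a gene counted as overlapped when any of its promoter peaks shared at least 1 bp with any peak of the other list.

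With 1 library per group no test between groups was possible and no p-value was computed. The 28 gene lists, holding 763 symbols of which 761 were matched, were fixed before the data were examined. They were mitotic kinesins, spindle checkpoint and kinetochore, centrosome and spindle poles, tubulins, G2 and M phase regulators, DNA replication, DNA damage response, p53 targets, apoptosis regulators, hepatocyte genes, liver progenitor and stemness genes, Wnt pathway and targets, immediate early genes, MAPK and PI3K signalling, NF-kB and interferon response, unfolded protein response, heat shock proteins, glycolysis, cholesterol and fatty acid synthesis, hypoxia response, ribosomal proteins, replication-dependent histones, Pol II transcription machinery, epithelial to mesenchymal transition, blood cell markers, neuronal markers, fibroblast and endothelial markers, and olfactory receptors. The number of members with a promoter peak in both lists was placed as a percentile among 10000 random lists of control promoter genes of the same size, matched on the 10 bins of control score. Such a percentile describes these libraries and is not a test.

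Named genes followed a rule set at the same time. It took KIF11, the 10 strongest control promoter genes with no drug peak annotated to them, the 10 likewise in drug, the 10 shared promoter genes with the best worse rank, and up to 2 shared and 2 unshared members per list. The rule broke ties in rank by fold, which the files lack, so ties were broken by position. A second set of 10 and 10 genes without overlap by position was added after the data had been seen, and further genes are marked where they were chosen by their values. Some genes that these rules take are not reported here. Alternatives were a stricter score, both lists at the length of the shorter one, merged neighbouring peaks, chromosomes 1 to 22 and X, other overlap rules, transcription start sites within 1 kb, any annotated peak, and, added later, position in place of name and removal of peaks in Alu repeats.

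For the closing section, the score of the strongest drug peak overlapping each control promoter was ranked among the 201 control promoter genes nearest in control score, giving a local percentile. Methods were tested on the real peak intervals and on simulated data. Between the real control and drug lists, overlap calls differed from bedtools 2.31.1 for 0 of the 49854 control peaks. Of unchanged random lists of 25 genes 6.5% fell outside the 2.5th to 97.5th percentiles, and of lists with overlap lowered to 50% of its level 79.0% fell under the 2.5th, in a simulation over 9106 genes. Over the same 9106 genes, 53.5% of promoters lowered 2-fold and 99.0% of those lowered 4-fold fell under the 5th local percentile. That simulation gave every promoter a drug score above 0. In the data weak control promoters often had no drug peak, 87.6% of genes in the weakest bin by position, so these shares do not cover them. Tables were handled in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.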

Results

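Chromatin profiles of PLC8024 liver cancer cells were collected by CUT&Tag from 1 control library and 1 library of cells given a drug at 10 nM for 6 hours. The series concerns target genes around KIF11, the motor protein that pushes spindle poles apart in mitosis. The control list held 49854 peaks and the drug list 29283. There were no replicates, so no difference between the libraries could be set against replicate spread. The number of reads behind each list was unknown. Peak scores quoted here are the authors' own and describe a peak within its own list.

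The first comparison asked how far the peaks of treated cells coincided with those of control cells. Promoters were the class most often found in both lists, with 74.4% of the control promoter peaks (95% interval 73.5 to 75.2) overlapped by a drug peak. Introns held 51.6% of the peaks found in control alone, and 24.7% of the 20470 control intron peaks were overlapped (24.2 to 25.3). Very few promoters were marked in the drug list alone, since 97.6% of its 8381 promoter peaks (97.3 to 97.9) overlapped a control peak. The drug list was 58.7% as long as the control list and covered 10292829 bp against 22020015 bp. Its peaks were narrower, with a median width of 259 bp against 345 bp, and 35.9% of them had the smallest width of 200 bp, against 13.8% in control.

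Over all classes, 40.1% of control peaks (39.7 to 40.5) shared at least 1 bp with a drug peak, which left 29867 control peaks without a partner. In the other direction 70.7% of drug peaks (70.2 to 71.3) overlapped a control peak and 8571 did not. Overlap followed strength within each list. Split into 10 equal bins of score, the weakest bin of the control list had 4.71% of peaks overlapped, the seventh 48.1%, and the strongest all but 1 of 4986. In the drug list the share went from 5.84% in the weakest bin to all 2929 peaks of the strongest. Drug peaks without a control partner had a median score of 26 and 88.4% were 200 bp wide. Control peaks without a drug partner had a median score of 55, against 286 for those with one.

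**Figure D1:**
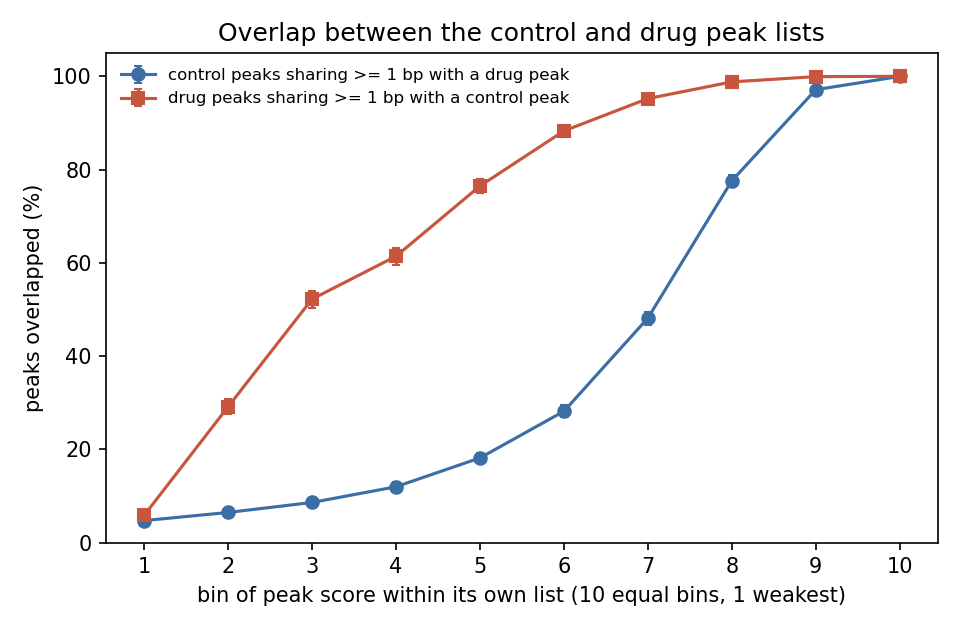
Percent of peaks sharing at least 1 bp with the other list (vertical axis) in each of 10 equal bins of peak score within a list (horizontal axis, 1 weakest), for control peaks (circles) and drug peaks (squares), with exact 95% intervals as bars. Overlap climbed from 4.71% to 99.98% across the control bins and from 5.84% to 100% across the drug bins.

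Promoter peaks numbered 9863 in control, 19.8% of the list (19.4 to 20.1), and 8381 in drug, 28.6% (28.1 to 29.1). The drug list thus held 85.0% as many promoter peaks as the control list and 52.3% as many peaks elsewhere. Peaks in exons numbered 2436 in control and 730 in drug, those in introns 20470 and 10069, and those in intergenic DNA 9249 and 5889. In 5' UTRs 69.9% of 595 control peaks were overlapped, and in 3' UTRs 22.5% of 1240. The higher promoter share in drug did not hold at equal list length, because the 29283 strongest control peaks were 29.8% promoter peaks against 28.6% in drug. Among chromosomes 1 to 22 and X, the overlapped share of control peaks ran from 30.8% on chromosome 22 (28.2 to 33.5) to 43.4% on chromosome 6 (41.4 to 45.5).

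**Figure D2:**
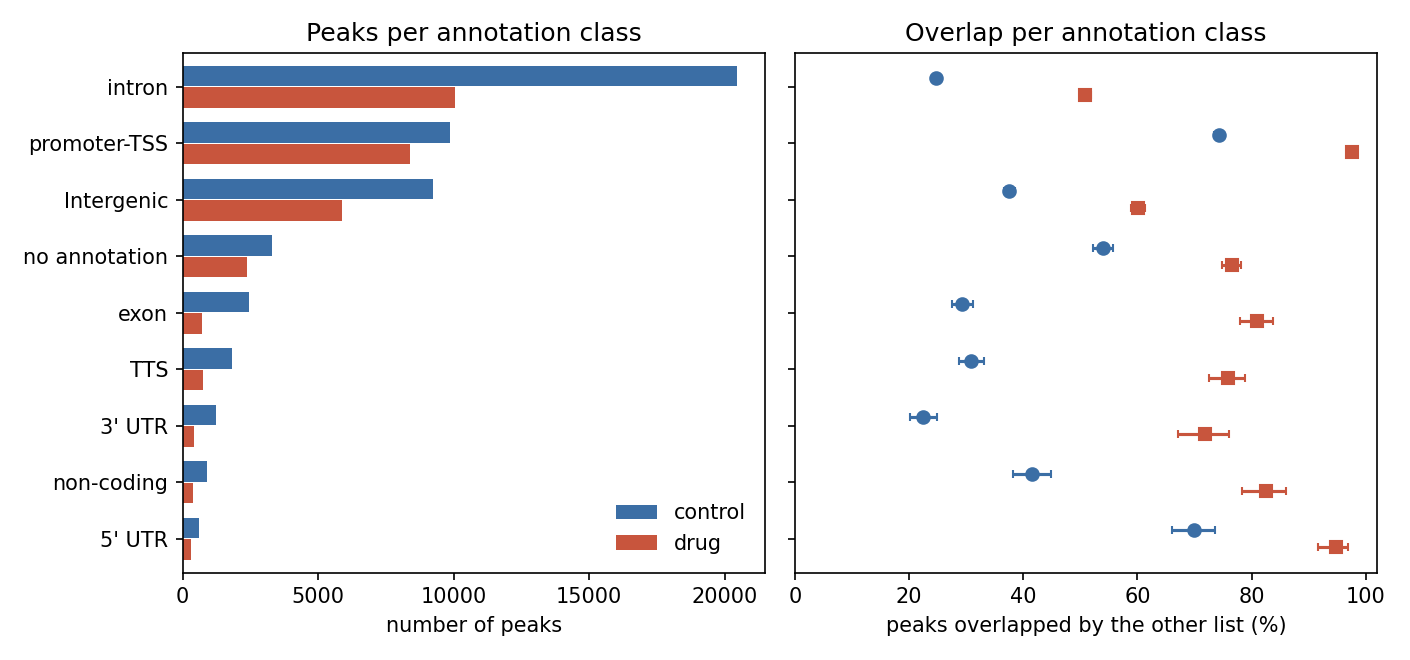
Left, number of peaks (horizontal axis) per annotation class in the control and drug lists. Right, percent of each class overlapped by the other list (horizontal axis) for control (circles) and drug (squares), with exact 95% intervals; promoter peaks lead among control peaks at 74.4%, and introns are lowest after 3' UTRs at 24.7%.

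At KIF11, whose gene body spans chromosome 10 from 92593130 to 92655395 in hg38, both libraries had a promoter peak at the transcription start site. The control peak lay at 92592869 to 92593537, was 669 bp wide, scored 586 and ranked 5096 of 49854, in the top 10.2% of its list. The drug peak lay inside it at 92592937 to 92593307, was 371 bp wide, scored 59 and ranked 14609 of 29283, in the top 49.9% of its list. The lists differ in length, so these ranks alone cannot show whether the signal changed. The drug score of KIF11 is set against promoters of similar control score in the closing section. The drug list held 2 further weak peaks annotated to KIF11 and absent from control, each 200 bp wide. The upstream peak, at 92588438 to 92588637 in an AluSg repeat, scored 14, and the peak at 92608347 to 92608546 in intron 4 of 21 scored 13.

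**Figure D3:**
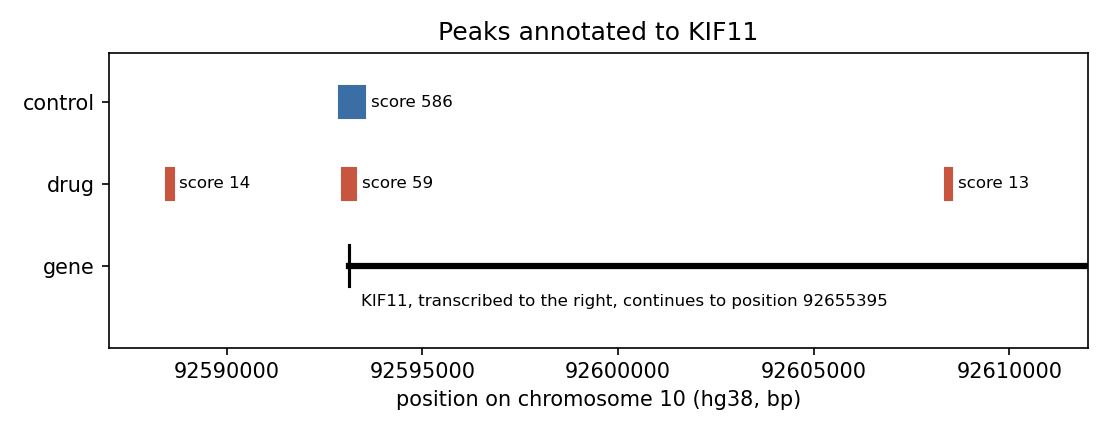
Position on chromosome 10 (horizontal axis, hg38) of the peaks annotated to KIF11 in the control and drug lists, drawn to scale with their scores, above the start of the gene. The drug promoter peak (score 59) lies inside the control promoter peak (score 586).

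The second comparison asked which genes had a promoter peak in each library. All genes in the top 3 of 10 equal bins of control promoter score, 911, 910 and 911 genes, had a drug peak at the same place. Among the shared genes with the best ranks in both lists were the translation elongation factor EEF1A1 (control score 6344, drug score 1942), the pyruvate carboxylase gene PC (4422 and 1840), the prenylation enzyme subunit RABGGTB (4200 and 1483), the vesicle transport GTPase RAB1A (3397 and 1451), the aminotransferase KYAT3 (3549 and 1367) and the histone gene H2BC11 (3474 and 1316). KRABD2, listed under its older name KRBA2, led them with 15779 and 7150. Its peak was 290 bp wide with exactly the same limits in both lists. Whether reads at KRABD2 were misplaced was not tested, so its values are uncertain. SRGAP2D, SRGAP2B and FAM72A also belonged to this set, but they have near-identical copies in the genome, and EEF1A1 has many processed pseudogenes, so reads at these genes may be misplaced and their values are uncertain.

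By gene name, 9106 genes had a control promoter peak, 7900 a drug promoter peak and 6569 both. Control alone held 2537 names, 27.9% of its genes (26.9 to 28.8), and drug alone 1331, 16.8% (16.03 to 17.7). Of the drug-only names 89.5% (87.7 to 91.1) and of the control-only names 22.8% (21.2 to 24.5) had a promoter peak that overlapped a peak of the other list. For 765 of these 1191 drug-only names (64.2%, 61.4 to 67.0) the overlapping control peak carried the same name in another annotation class, and for 405 (34.0%) it was a promoter peak under another name or none. For the 578 control-only names the numbers were 206 (35.6%) and 366 (63.3%, 59.2 to 67.3). By position, 2030 control genes (22.3%, 21.4 to 23.2) had no drug peak at their promoter, and 166 drug genes (2.10%, 1.80 to 2.44) had no control peak. In the weakest of the 10 bins of control promoter genes 12.4% were overlapped by position, in the fifth 93.4%, and in the seventh all but 3 of 910.

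Among control-only names with no drug peak of any class annotated to them, the strongest were PDIA4, DDX42, DBF4, NDUFA2, H3C14, H2AC20, PPP2R5A, ANKHD1, H2AC15 and HAUS3, with control scores from 2803 down to 1875. All 10 overlapped a drug peak that carried another name or none. Among drug-only names with no control peak of any class annotated to them, the strongest were H2AC18, LSS, ANKHD1-EIF4EBP3, TBC1D17, IQCH, TCTA, CRYZL1, C8orf44-SGK3, KLHDC3 and POLN, with drug scores from 860 down to 613, and all 10 overlapped a control peak. DBF4, the activator of a replication kinase, was named SLC25A40 in the drug list, DDX42 was named CCDC47, and HAUS3, a spindle augmin subunit, was named POLN. TCTA was named RHOA in the control list and TBC1D17 was named AKT1S1.

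By position, the strongest control promoters without a drug peak belonged to UBQLN4 (chromosome 1, 156053759 to 156054263, score 505), TSPAN14 (score 486), PGLS, an enzyme of the pentose phosphate pathway (score 486), ANKRD46, SLC2A13, ZBTB24, UBE2F, LAMTOR3, ZNRF1 and SARM1 (score 371). UBQLN4 ranked 6023 in its list, within the top 12.1%. The strongest drug promoters without a control peak were weak in their own list, from EPHA2, a receptor tyrosine kinase (chromosome 1, 16155991 to 16156208, score 83, rank 11182), through UBTF (score 68), CYP27C1, BEST3 and MAP2K5, to TSPAN12 (score 65). NPIPB3, GOLGA6L22 and GOLGA6L25 were also in that set and belong to families of near-identical copies, so their positions are uncertain. These genes were taken by a rule added after the data had been seen.

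Genes of mitosis had a drug peak at most of their control promoters. Of 15 mitotic kinesins with a control promoter peak, 14 were overlapped by position and 12 shared a name, among them KIF24 (control score 1120, drug score 321) and KIF20B (809 and 191). KIF18A (1196) and CENPE (218) were control-only by name but overlapped a drug peak, and KIF4B (104) was not overlapped. Of 25 spindle checkpoint and kinetochore genes, 22 were overlapped, led by CENPA, the centromeric histone H3 (1272 and 199), and MAD2L1 (1093 and 291), while BIRC5 (306), MAD2L2 (291) and TRIP13 (97) were not. Centrosome and spindle pole genes were overlapped in 21 of 23, with CEP192 (1989 and 527) and NUMA1 (1829 and 505) strongest and TUBG1 (77) and HAUS1 (46) not overlapped. All 21 G2 and M phase regulators were overlapped, with CDC25C (1857 and 658) and ANAPC5 (1595 and 523) first. Tubulins had 4 of 7 overlapped, including TUBB4B (1311 and 341), and TUBG1, TUBB3 and TUBB2B were without a drug peak at control scores of 77, 74 and 49.

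Replication, repair and growth control genes likewise had a drug peak at most of their control promoters. DNA replication genes were overlapped in 25 of 27, with MCM4 (1749 and 446) and CDC6 (1683 and 383) strongest and RFC2 (140) and RFC4 (84) without a drug peak. DNA damage response genes were overlapped in 16 of 16, led by H2AX (2503 and 888). Of the p53 targets 19 of 20 were overlapped, led by CCNG1 (1759 and 674) and GADD45A (1756 and 387), with ZMAT3 (79) the exception. Apoptosis regulators had 14 of 16, led by CYCS (2269 and 586) and XIAP (1252 and 299), with BCL2 (67) and BIK (16) not overlapped. Immediate early genes had 19 of 20, led by JUN (3091 and 1311) and KLF6 (2206 and 816), with EGR3 (47) the exception. MAPK and PI3K signalling genes had 22 of 24, with ARAF (1761 and 509) strongest and MAPK3 (45) among those not overlapped. NF-kB and interferon response genes had 11 of 13, with NFKB2 (1370 and 333) strongest and NFKB1 (140) and IFIT1 (91) not overlapped. Pol II transcription machinery genes had 27 of 28, led by TBP (1349 and 385) and POLR2A (1125 and 358), with POLR2C (122) the exception.

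Of 36 hepatocyte genes, 18 had a control promoter peak and 13 of these were overlapped, including CPS1 of the urea cycle (1196 and 389). FOXA1 (98), GPC3 (96), ONECUT1 (60) and FOXA3 (58) were among those not overlapped. Albumin (ALB) and alpha-fetoprotein (AFP) had no promoter peak in either list. Peaks of another class were annotated to ALB in control alone and to AFP in both lists. Liver progenitor and stemness genes were overlapped in 7 of 10, with CD24 (895 and 271) and MYC (616 and 164) strongest and ANPEP (125) among those not overlapped. Wnt pathway genes and targets had 11 of 15, led by GSK3B (1351 and 406) and TCF7L2 (1236 and 382), with TCF7 (182), FZD7 (87), DVL3 (56) and LEF1 (28) not overlapped. Epithelial to mesenchymal transition genes had 9 of 10, led by TGFBR2 (1285 and 457), with TGFB1 (186) the exception.

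Among metabolic and stress genes, glycolysis had 13 of 17 overlapped, led by PGK1 (2078 and 671) and PGAM1 (1617 and 425), with SLC2A3 (138) and HK1 (70) not overlapped. Cholesterol and fatty acid synthesis genes had 18 of 19, led by PMVK (2457 and 695), with ELOVL6 (81) the exception. Hypoxia response genes had 12 of 13, led by ARNT (1867 and 778) and KDM3A (1343 and 622), with CA9 (67) the exception. Unfolded protein response genes had 17 of 18, led among shared names by CANX (2448 and 1209) and HSPA5 (2346 and 860), with TRIB3 (57) the exception. All 15 heat shock protein genes were overlapped, led by HSPD1 (3146 and 1160) and HSP90AB1 (2425 and 932). Ribosomal protein genes were overlapped in 36 of 36 by position and 34 by name, led by RPS12 (2274 and 906) and RPLP1 (1718 and 472). Replication-dependent histone genes, which stand in close pairs, were overlapped in 20 of 20 by position and 15 of 20 by name, led by H2BC11 and H2BC12 (2631 and 620).

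Matched for control strength, by position 0 of the 24 lists with at least 5 control promoter genes fell under the 2.5th or above the 97.5th percentile of random lists. Many lists could not pass the upper bound, because nearly all strong control promoters were overlapped. With every member overlapped, heat shock protein genes stood only at the 60.2nd percentile and ribosomal protein genes at the 70.3rd. Hepatocyte genes stood at the 44.2nd percentile, where random lists had a median of 13 overlapped, mitotic kinesins at the 87.9th and spindle checkpoint and kinetochore genes at the 21.9th. By name, replication-dependent histones stood at the 2.01st percentile and G2 and M phase regulators, MAPK and PI3K signalling and Pol II transcription machinery at the 99.0th, 98.7th and 99.0th. Over all lists, 387 of 444 control promoter genes were shared by name and 403 by position.

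**Figure D4:**
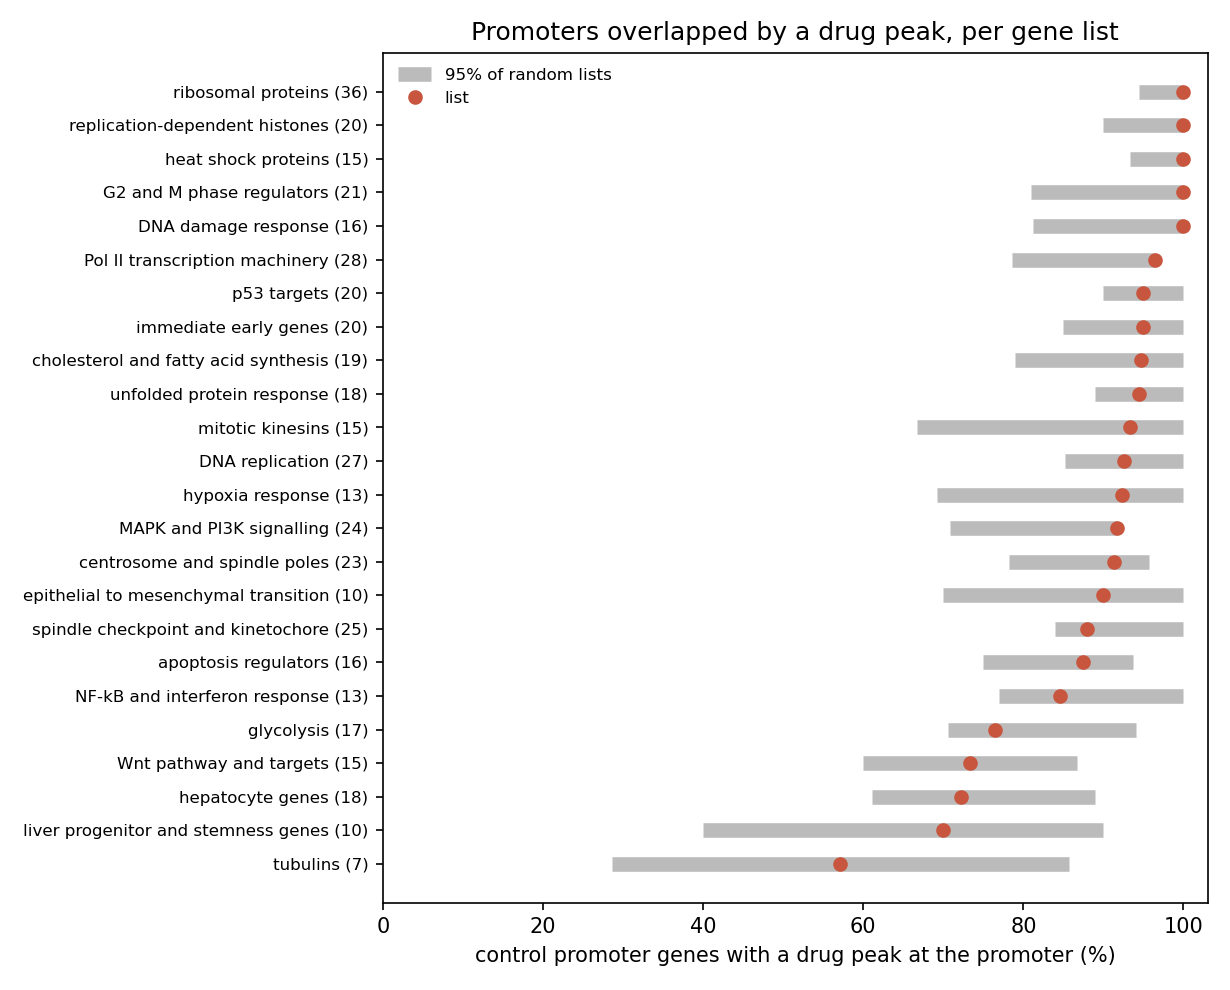
Percent of control promoter genes with a drug peak at the promoter (horizontal axis) for each gene list with at least 5 such genes (number in brackets), as points, with the range of the middle 95% of 10000 random lists matched on control score as grey bars. No list lies outside its bar.

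Markers of cell types other than liver cancer cells had few promoter peaks. In control 1 of 20 blood cell markers (CD8A, score 22, overlapped), 1 of 18 fibroblast and endothelial markers (PDGFRA, score 120, not overlapped) and 4 of 22 neuronal markers had a promoter peak. SNAP25 (628 and 279) and SYP (309 and 73) were in both lists, and SYN1 (189) and TUBB3 (74) were in control alone. The drug list added COL1A2 at a score of 15. Of 42 olfactory receptor genes 0 had a promoter peak in either list.

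Peaks centred in Alu repeats numbered 436 in control and 1360 in drug. Of the drug Alu peaks 1068 had no control partner, and 99.4% of those were 200 bp wide. The 30 strongest peaks of each list all lay in Alu repeats, and 27 of those in control overlapped 1 of the 30 in drug. The strongest peak in both lists, at 98631481 to 98631853 on chromosome 12, lay in an AluSq2 repeat in an intron near IKBIP and scored 199677 in control and 129709 in drug. Alu copies resemble each other in sequence, so reads there may belong to other copies and the positions are uncertain. Peaks centred in tRNA genes numbered 59 in control and 42 in drug, and those in snRNA genes 11 and 17. Simple repeats held 246 control and 379 drug peaks, L1 repeats 50 and 87, L2 repeats 254 and 122, and MIR repeats 221 and 110.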

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

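The tests of the Alu shares and of the drug treatment, and the matching on exact score, score bins and width, were chosen after the results were seen, and the other tests here were written before.

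Sequences other than chromosomes 1 to 22, X and Y held 8.07% of the drug peaks (7.76 to 8.39) and 6.59% of the control peaks (6.37 to 6.81), and they entered no comparison of genes because the files carry no annotation there. Of the 3286 control peaks on such sequences 53.9% (52.2 to 55.6) were overlapped by a drug peak.

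The drug list was shorter than the control list, and intron peaks were overlapped less often than promoter peaks. A lower read yield in the drug library as the whole cause would treat promoters and introns of equal strength alike. Promoter peaks were overlapped 8.13 percentage points (6.50 to 9.75) more often than intron peaks over the 6th to 9th of 10 bins of control score, beyond the 5 points set in advance. That difference was 6.82 points (5.20 to 8.44) at exactly equal score, 6.73 (5.14 to 8.32) within narrow bins of score and 4.80 (3.14 to 6.46) within the same bins of score with width binned too, where the bound was no longer passed, and an equal score is not an equal number of reads. Lower yield as the whole cause and the drug treatment therefore cannot be told apart with 1 library per group and unknown depth.

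The drug list held more Alu peaks than the control list, 1360 against 436, and also more peaks in simple repeats, 379 against 246, and in L1 repeats, 87 against 50. Among peaks scoring at least 50 the ratio of numbers was 1.14 (0.980 to 1.34), with 357 against 312, but Alu peaks were 2.11% (1.90 to 2.34) of such drug peaks and 0.873% (0.780 to 0.975) of such control peaks, so weak peaks near the threshold stay open as an explanation. A rise in weak peaks of every kind alike would give similar Alu shares among peaks without a partner. Alu repeats held 12.5% of such drug peaks and 0.885% of such control peaks scoring under 50, a difference of 11.6 points (10.7 to 12.4). The pattern itself largely set this outcome, because 1068 of the 1360 drug Alu peaks had no control partner. The drug peaks were also not limited by score, so the comparison is no separate test. Reads misplaced among similar copies were not tested, and the drug treatment stays open with 1 library per group.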

How the results depend on the processing

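Position in place of name and removal of Alu peaks were chosen after seeing the data. No paired analysis was possible because both groups share only replicate number 1 and no test was made. The alternative of fold enrichment of at least 5 was not run, since the files hold no fold, and merging peaks within 100 bp changed nothing because no peaks lay that close, so it says nothing about stability. Depth was unknown and limits every count. In each alternative the control list was as long as the drug list or longer, and control peaks were overlapped less often than drug peaks. Overlapped peaks were close in number as deposited, 19987 in control and 20712 in drug, so the longer control list largely sets its lower share. At equal length the first statement was fixed by the step itself. Neither statement therefore says much about stability. The higher promoter share in drug turned to a lower one with both lists at 29283 peaks, 29.8% in control against 28.6%, since that step removes only weak control peaks, which are rarely promoter peaks, and it held in the other alternatives.

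At −log10 q of at least 5 the drug list had 16902 peaks, overlapped shares were 42.7% of control and 92.6% of drug peaks, promoter shares 25.7% and 42.8%, and shared names over all gene lists 81.8%. At equal length overlapped shares were 62.6% and 65.2%. On chromosomes 1 to 22 and X overlapped shares were 39.1% and 70.2%, and promoter shares 21.2% and 31.2%. Requiring 50% of both peaks gave 29.7% and 50.6%, and allowing 1 kb gave 46.4% and 73.6%. With start sites within 1 kb promoter shares were 26.8% and 34.8%, and 645 drug genes had no control promoter peak. With any annotated peak 16988 control and 14596 drug genes had a peak, 13097 both, and 3891 control genes had none in drug. Without Alu peaks 73.1% of drug peaks were overlapped and 30.01% were promoter peaks. By position 166 drug genes had no control peak, and 90.8% of list genes were overlapped. For single gene lists the share moved outside its interval in 3 of 27 lists by position, 2 of 27 with any annotated peak, 1 of 26 at equal length and 0 under the stricter score or start sites within 1 kb. Each list that moved had reached 100%, which lies above any exact interval of a lower share. By position these were DNA damage response, ribosomal protein and replication-dependent histone genes, whose control-only names all overlapped a drug peak. The cause of the other movements was not tested.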

Other observations

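The local percentile used here was chosen after the data had been seen, as were the genes singled out by it and the tests of the drug treatment and of chance, while the test of the region around KIF11 was written before its result. It ranks the drug score at each control promoter among the 201 control promoter genes nearest in control score. It therefore describes order within the drug list and cannot by itself show whether a signal changed. Control promoters without a drug peak share a drug score of 0 and take the middle of their tied ranks. Weak control promoters without a drug peak, such as those of BIK and LEF1, both at 46.5, therefore could not rank low. The random lists used below should not be read as matched on control score. Their bounds were 30.6 and 71.4 for the 15 heat shock protein genes and 30.3 and 71.9 for the 15 Wnt genes. The median control scores of these lists were 953 and 399. Heat shock protein genes, all overlapped, stood at the 59.7th percentile with a median of 47.0. Weak tied promoters may pull the random medians down, so percentiles of strong lists may be too high.

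The median local percentile of 18 unfolded protein response genes, which include chaperones, stress sensors and transcription factors, was 72.4, with 14 members above 50. That median stood at the 98.9th percentile of random lists, which may be too high because the list had a median control score of 1102.5. The lectin chaperone gene CANX stood at 88.3, the unfolded protein sensor gene ERN1 at 87.3, PDIA4 at 83.8, EDEM1 at 82.8, HSPA5 at 68.7, ATF4 at 47.3, DDIT3 at 45.5 and PDIA6 at 35.3. Cholesterol and fatty acid synthesis genes had a median of 68.9, at the 97.3rd percentile, which may likewise be too high. FDFT1 stood at 92.3 and FASN at 86.8, but SQLE at 0.746. The stress-induced chaperone genes DNAJB1 and HSPA1B stood at 99.8 each, the highest values among list members, though HSPA1B has a near-identical neighbour copy, and all 15 heat shock protein genes together had a median of 47.0.

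Spindle checkpoint and kinetochore genes ranked low, with a median of 33.8 over 25 genes at the 1.63rd percentile of random lists and 18 members below 50. CENPA stood at 0.746, BIRC5 at 3.73, MAD2L2 at 4.23, NSL1 at 8.21 and CENPF at 11.2, while MIS12 stood at 99.0 and AURKB at 76.4. Mitotic kinesins had a median of 37.1 over 15 genes, at the 11.8th percentile, and went both ways, with KIFC1 at 99.3 and KIF4A at 98.8 against KIF14 at 12.2 and KIF11 at 0.249. KIFC1 and HSPA1B lie on chromosome 6 in a stretch where MDC1 (98.8), RPS18 (93.8) and TUBB (86.6), members of other lists, also ranked high. BAK1, also near KIFC1, stood at 26.6, and whether the region set these ranks was not tested. Epithelial to mesenchymal transition genes had a median of 28.7 over 10 genes, at the 3rd percentile. Of 24 lists, 1 lay under the 2.5th percentile and 1 above the 97.5th, where chance gives 1.2 in all, so the number of such lists was close to what chance gives. These random lists should not be read as matched on control score, so the count is approximate.

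KIF11 had the lowest drug score, 59, of the 201 control promoters with control scores from 566 to 606, whose median drug score was 166 (quartiles 130 and 217) and whose next lowest was 63. A loss over most of the region within 5 Mb of KIF11 was predicted to give a low median local percentile there. The other 42 control promoter genes there had a median of 45.0 (34.6 to 53.7), above the bound set in advance. Weak promoters without a drug peak take tied middle ranks and can hold this median up, so it cannot settle that question. The upper quartile of 72.6 argues against a loss at every promoter there. Neither value can show a loss over a shorter stretch that holds few genes. Of 9106 control promoter genes 19, or 0.209%, ranked as low. Ranking within 201 genes largely sets such a share, and weak promoters tied at a drug score of 0 could not rank as low. The share therefore does not measure chance. Chance among many promoters may still account for the rank of KIF11, although KIF11 was named before the data were examined. A lower CUT&Tag signal at the KIF11 promoter after the drug treatment is a hypothesis that 1 library per group leaves open. The antibody was not named, so the protein or mark behind that signal is unknown.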
